A study of Homo sapiens with 4 samples.

How the data were processed

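RNA was sequenced from A2780, an established human ovarian cancer cell line, in 4 libraries, all labelled WT. The labels put 2 of them in a vehicle group treated with DMSO (numbered 1 and 2), with no treatment time given. They put 2 in a group treated with wogonin (numbered 3 and 4), a flavone, at 10 ug/mL for 48 h. Per the labels' protocols, RNA was taken up with a column kit and libraries were made with a SMARTER mRNA kit. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here. The submitters' processing notes name the builds GRCh 37 and hg 19, and all coordinates given here are those of the deposited files.

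For each library the authors deposited 1 table of 57773 genes. Per the file headers, it holds counts of reads per gene in exons and in introns, each as a total and as the part that matched a single place. It also holds TPM and RPKM values that the authors computed from the exon counts and exon lengths, and a fraction of unique over total reads and of intron over gene reads, per the file headers. The exon and intron counts of a row added up to its gene count in every row. In 20986 genes the deposited table lists no exons, and all of their counts stand in the intron column. The total exon counts were used as deposited for the main tests. The other count columns served as alternatives. TPM, RPKM and the fractions were used only to check the files.

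Total exon reads were 11478731 and 11839562 in DMSO 1 and 2, and 11005921 and 11287570 in wogonin 3 and 4. At these depths 3 counts, the floor used here, were worth between 0.253 and 0.273 CPM (counts scaled to a library of 1000000 reads). Intervals of shares are 95% Wilson intervals, and intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No 2 libraries were copies of each other: the chi-square of exon counts over its degrees of freedom was 2.98 for the DMSO pair, 7.20 for the wogonin pair and between 55.5 and 60.2 for pairs across groups. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. An exact permutation test of 2 against 2 libraries cannot go below 0.333, so differences rest on models that share the spread across genes.

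Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, robust quasi-likelihood fit with treatment as its single term, 2-sided test), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. This version of edgeR runs the older quasi-likelihood method by default. Before the data were examined, 39 gene lists were fixed, and each list with 5 or more tested members was tested with camera (limma 3.58.1) on voom log2 CPM with a preset correlation between genes of 0.01. List p-values were adjusted over the lists. Camera with an estimated correlation and fry were run beside it. With 4 libraries the estimated correlation leaves camera few degrees of freedom and little power, so a list that fails there is left undecided. Fry's directional test asks whether the genes of a list move, on balance, one way and does not compare them with other genes. Members were also adjusted over the list alone.

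The rule for genes named in the report was fixed before the data were examined. It takes the 8 largest rises and 8 largest falls in log2 fold change among genes past the threshold with a mean of at least 3 log2 CPM and no overlap between the groups, leaving out clone names and small RNA families. It adds up to 3 members of each list with the smallest adjusted p, of which the text leaves some out. It also adds TET1, TET2, TET3, TDG, DNMT1, DNMT3A, DNMT3B, PRKAA1, PRKAA2, CDKN1A and MYC whatever their p. Further members named in a list's account were chosen after their values were seen. Standard errors are those of the log2 fold change, and a mean ± SD is over the 2 libraries of a group in TMM-scaled CPM.

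Alternatives fixed before the data were examined were size factors of the DESeq2 kind, library totals alone, no filter and a stricter one with a mean of at least 10 counts, DESeq2 1.42.0, limma-voom, a non-robust fit, the other 3 count columns, an exon length trend removed from each library (a smoother with a span of 0.3), a size threshold of 1 log2 unit, and leaving out each library in turn. Upper-quartile scaling, the newer quasi-likelihood method, the removal of mitochondrial genes and the removal of a GC trend were chosen after seeing the data. GC content came from GENCODE transcripts of another build, matched by gene ID, with a value for 97.9% of the genes tested. No coordinates of that build were used. Both trends were fitted to counts over library totals, and the TMM factors were then applied on top. The scaling between groups was thus corrected more than once in these settings.

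The gene test was checked on simulated counts drawn with the means and totals of these libraries, with 200 of the genes changed. Over the 13199 simulated genes tested, changes of 0.5 and 1 log2 units were called in the right direction for 71.2% and 78.8% of the changed genes, changes of 0.25 for 6.15%, and none of the 103 calls was false. Far fewer genes changed there than were called in the data (63.8% of those tested), so the adjusted threshold was stricter in the simulation. Its rates do not carry over to the calls below, and it does not test the scaling. Intron reads were set against exon reads of the same gene in 1 edgeR model with the library as a block and an interaction of read type and treatment, over coding genes with a mean of at least 10 reads of each type. On simulated data that model recovered 25.8% of ratio changes of 1 log2 unit and 95.4% of those of 2, with 5 unchanged genes among 112 calls in 8470 genes. Plots were drawn with matplotlib 3.10.9.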

Results

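Transcript levels were measured by RNA sequencing in A2780 ovarian cancer cells after treatment with wogonin (2 libraries) or with its vehicle DMSO (2 libraries). The study's question is whether wogonin, a plant flavone, acts on ovarian cancer growth through DNA demethylation. The series title names AMPK, TET2 and hydroxymethylcytosine as the axis in question. These libraries measure transcript levels only, so they cannot answer that question about growth or DNA methylation. Each library held between 11005921 and 11839562 exon reads. Mitochondrial genes took 1.65% and 1.45% of exon reads in DMSO 1 and 2, 1.67% in wogonin 3 and 3.03% in wogonin 4 (95% Wilson interval 3.02 to 3.04%). Introns took 7.96% of the reads of genes with exons in wogonin 3 (95% Wilson interval 7.95 to 7.98%), against 5.26%, 5.29% and 5.61% in DMSO 1, DMSO 2 and wogonin 4.

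Many expressed genes differed in level between the wogonin and the DMSO libraries. Of 13449 genes tested, 4343 were higher and 4234 were lower in the treated cells at a Benjamini-Hochberg adjusted p under 0.05 (edgeR quasi-likelihood test), which is 63.8% of the genes. DESeq2 called 6701 of the same 13449 genes. The change reached 1 log2 unit or more for 849 of the higher and 1337 of the lower genes. That split depended on the scaling. It was 703 and 1578 with library totals alone and 704 and 1576 with upper-quartile scaling, which moved the median of all genes to -0.09. It was 1071 and 1099 with an exon length trend or 1051 and 1098 with a GC trend removed, which moved that median to 0.11. The trend settings corrected the scaling between groups more than once, so their splits do not show a length or GC effect. The median size among changed genes was 0.62 log2 units. In 11015 genes (81.9%) the 2 treated libraries lay on 1 side of both DMSO libraries. Chance gives 33.3% only if all libraries are independent, which the labels do not say. If libraries of a group share a culture, differences between cultures raise that share without any treatment effect. The spread between libraries of a group was small, with a common coefficient of variation of 5.60%.

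Among genes past the threshold with a mean of at least 3 log2 CPM and no overlap between groups, the 8 largest rises were led by FCGBP (ENSG00000090920, chromosome 19, 40353963 to 40440533), which encodes a mucin-associated protein. Its level was 2.97 ± 1.08 CPM in DMSO and 60.6 ± 9.71 CPM in wogonin (SD, n = 2 each), a log2 fold change of 4.35 ± 0.20 (SE, edgeR adjusted p = 1.7e-08). TSPAN31, a tetraspanin (ENSG00000135452, chromosome 12, 58131796 to 58143994), rose by a log2 fold change of 4.18, from 3.07 ± 0.39 to 55.9 ± 2.01 CPM. The gene overlaps AGAP2 and CDK4, which lie on the opposite strand. The transcription factor TBX4 (log2 fold change 3.17), the matrix gene TNXB (3.11), the vesicle transport gene SYTL2 (2.96), FAM154B (2.94), the decoy receptor TNFRSF10D (2.77) and the fatty acid hydroxylase CYP4V2 (2.50) followed. TNXB overlaps ATF6B on the same strand, which fell by 2.57 on the log2 scale, and the TNXB log2 fold change was 3.15 in uniquely placed exon reads. For CYP4V2 the value was 1.66 in uniquely placed gene reads, which include introns.

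Within the same limits, UBALD2 showed the largest fall (ENSG00000185262, chromosome 17, 74261283 to 74267375), from 33.6 ± 0.93 to 2.18 ± 0.70 CPM, a log2 fold change of -3.94 ± 0.17 (SE, edgeR adjusted p = 3.1e-11). KLHL24, a substrate adaptor of a ubiquitin ligase (ENSG00000114796, chromosome 3, 183353356 to 183402265), fell from 54.7 ± 7.37 to 4.59 ± 0.0258 CPM. The other falls were those of MTURN (log2 fold change -3.21), the clock output transcription factor DBP (-3.13), EFHD1 (-2.97), YPEL2 (-2.93), the secreted metabolic hormone FGF21 (-2.87) and the transcription factor KLF9 (-2.81). BMF, below that level, went from 69 and 52 reads in DMSO to 1 read in each wogonin library. DBP overlaps SPHK2 on the opposite strand, and EFHD1 overlaps AC073254.1.

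Among the genes that the study's question names, the transcript of TET2, an enzyme that oxidises 5-methylcytosine, was lower after wogonin. Transcript levels do not measure TET2 protein, its activity or hydroxymethylcytosine. TET2 (ENSG00000168769, chromosome 4, 106067032 to 106200973) stood at 45.0 ± 3.93 CPM in DMSO and 22.3 ± 1.31 CPM in wogonin, a log2 fold change of -1.01 ± 0.10 (SE, edgeR adjusted p = 3.3e-07). TET1 (ENSG00000138336, chromosome 10, 70320413 to 70454239) fell by 0.80 on the log2 scale (SE 0.14, edgeR adjusted p = 3.1e-04), from 39.3 ± 1.27 to 22.7 ± 5.57 CPM. TET3 was at 63.0 ± 1.14 and 61.7 ± 2.88 CPM (log2 fold change -0.03, edgeR adjusted p = 0.75), and the glycosylase TDG had a log2 fold change of -0.14 (edgeR adjusted p = 0.15). DNMT3B, a de novo DNA methyltransferase (ENSG00000088305, chromosome 20, 31350191 to 31397162), fell from 43.1 ± 3.31 to 18.1 ± 0.70 CPM, a log2 fold change of -1.25 (edgeR adjusted p = 3.9e-08). DNMT3A rose by a log2 fold change of 0.49 (edgeR adjusted p = 0.0036), a call lost with DESeq2 (adjusted p = 0.058) and in gene reads that include introns (0.21 in total and 0.22 in unique gene reads, edgeR adjusted p = 0.17 and 0.14). The maintenance methyltransferase DNMT1 was at 264 ± 11.5 and 269 ± 0.49 CPM (edgeR adjusted p = 0.70).

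**Figure D1:**
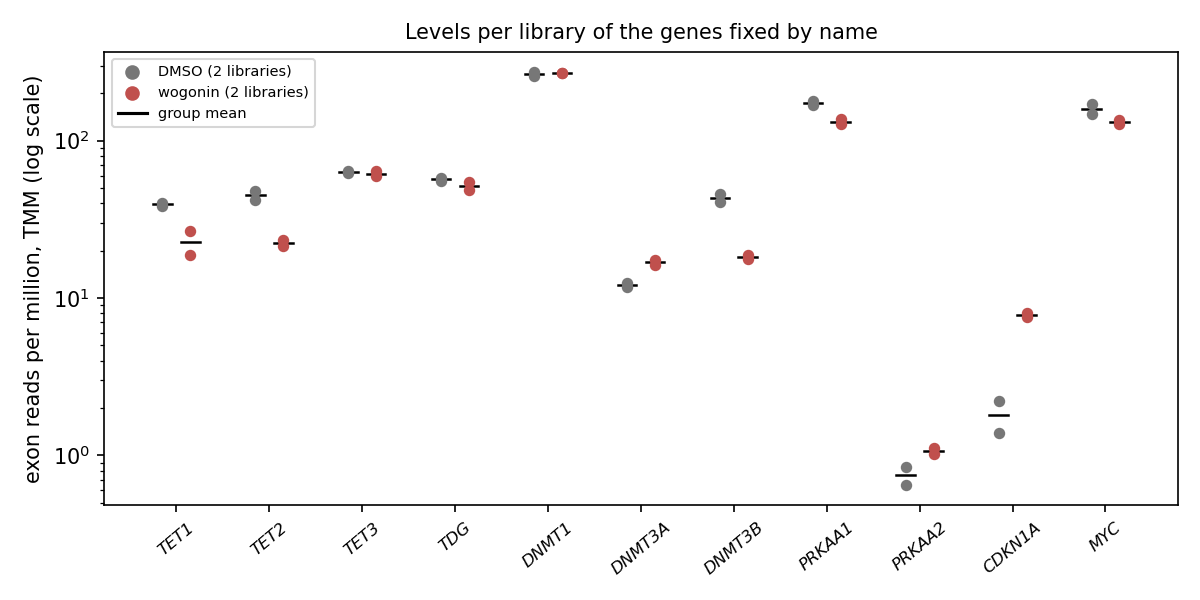
Levels of 11 genes fixed by name in CPM of exon reads after TMM scaling (log axis), with 1 point per library and a bar at each group's mean. TET1, TET2 and DNMT3B were lower in both wogonin libraries than in both DMSO libraries, while the points of TET3 and DNMT1 overlapped.

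Of 29 tested members of the DNA methylation and demethylation list, 12 fell, 4 rose and 13 did not pass, and the counts were the same when adjusted over the list alone. GADD45B fell by 2.19 on the log2 scale, the methyl-CpG binding protein ZBTB38 by 1.66, and the TET2 regulator CXXC4 by 1.62. Rises included those of NEIL2 (0.60), DNMT3A and MBD2 (0.27). The list as a whole did not pass the camera test (adjusted p = 0.081, and 0.64 with an estimated correlation). Fry's directional test, which does not compare the list with other genes, called it lower (fry adjusted p = 0.016). By camera the result depended on the setting. The list passed camera, as lower, in 6 of 15 alternatives. Those 6 were library totals alone, the other 3 count columns, and the fits without wogonin 3 (adjusted p = 0.044) or without wogonin 4 (adjusted p = 0.0145).

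The catalytic AMPK subunit PRKAA1 (ENSG00000132356, chromosome 5, 40759481 to 40798476) fell from 174 ± 7.55 to 132 ± 6.67 CPM, a log2 fold change of -0.40 (edgeR adjusted p = 4.7e-05). With a GC trend removed, a setting chosen after seeing the data, the value was -0.23 and still passed. That setting moved the median of all genes to 0.11. PRKAA2 was near 1 CPM in both groups (0.75 ± 0.14 and 1.07 ± 0.06) and did not pass (edgeR adjusted p = 0.35). Among 19 tested AMPK subunits and upstream regulators, 6 rose and 6 fell (camera adjusted p = 0.81). The kinase gene MAP3K7 rose by a log2 fold change of 0.68 and the phosphatase gene PPM1A fell by 0.71. Transcript levels do not measure AMPK activity, which depends on phosphorylation.

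Genes of mitosis fell together. Of 36 tested G2 and mitosis genes, 33 were lower, none was higher and 3 did not pass, with a median log2 fold change of -0.92 (camera adjusted p = 1.5e-14, and adjusted p = 0.64 with an estimated correlation). KIF20A, a kinesin of cytokinesis (ENSG00000112984, chromosome 5, 137514408 to 137523404), fell from 196 ± 3.17 to 32.3 ± 0.87 CPM. NUSAP1 fell by 1.58 and TOP2A by 1.29 on the log2 scale. Genes of DNA replication went both ways, with 22 of 40 higher and 12 lower (camera adjusted p = 0.12): MCM4 rose by a log2 fold change of 0.77 and FEN1 by 1.01, while RRM2 fell by 1.02. CDKN1A, the cyclin-dependent kinase inhibitor p21, was low but higher in treated cells, at 1.80 ± 0.58 and 7.79 ± 0.33 CPM (log2 fold change 2.12, edgeR adjusted p = 3.0e-06). The p53 target list as a whole did not pass (6 higher and 13 lower of 28, camera adjusted p = 0.20). MYC fell by 0.27 (edgeR adjusted p = 0.0052). The call did not hold without DMSO 1, where the value was -0.17. It was also lost with an exon length trend removed (value -0.14, edgeR adjusted p = 0.13), which moved the median of all genes to 0.11.

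Lipid synthesis genes rose. In the cholesterol list 21 of 24 tested genes were higher and 2, TM7SF2 and STARD4, were lower, with a median of 0.87 (camera adjusted p = 9.3e-08, and adjusted p = 0.64 with an estimated correlation). DHCR7, which makes the last step to cholesterol (ENSG00000172893, chromosome 11, 71139239 to 71163914), rose from 183 ± 12.4 to 541 ± 27.4 CPM. HMGCS1 rose by a log2 fold change of 1.15. In the fatty acid synthesis list 13 of 19 were higher and 3 lower (camera adjusted p = 0.0031, and adjusted p = 0.64 with an estimated correlation), and 4 were lower when adjusted over the list alone. The desaturase SCD had the smallest adjusted p of this list and rose by a log2 fold change of 1.76 ± 0.05 (SE, edgeR adjusted p = 1.2e-12), while ACSS2 rose by 1.27 and ELOVL6 by 1.07.

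Of 33 nuclear-encoded genes of oxidative phosphorylation, 23 rose and none fell, with a median of 0.29 (camera adjusted p = 6.4e-04, and adjusted p = 0.64 with an estimated correlation). UQCRH rose by a log2 fold change of 0.76. The 13 genes encoded in mitochondria had a median of 0.70 (camera adjusted p = 0.015, and adjusted p = 0.64 with an estimated correlation), but 1 of them, MT-ND3, passed on its own, and none did when adjusted over the list alone. That median was 0.18 without wogonin 4, the library with the high mitochondrial share, and 1.15 without wogonin 3, and the call of MT-ND3 was lost without either treated library (edgeR adjusted p = 0.21 and 0.19). Glycolysis genes had a median of 0.19, with 13 of 22 higher and 3 lower (camera adjusted p = 0.031, and adjusted p = 0.64 with an estimated correlation). The call was lost in 5 of 15 alternatives, whose adjusted p ranged from 0.013 to 0.13: library totals alone (median 0.09), total and unique gene reads (0.11 and 0.12), upper-quartile scaling (0.09) and the fit without DMSO 2 (median 0.18, adjusted p = 0.056). Library totals alone and upper-quartile scaling moved the median of all genes to -0.09. ALDOA rose by a log2 fold change of 0.80 and HK1 by 0.81, and PDK1, a brake on pyruvate oxidation, fell by 0.86. The fatty acid oxidation list did not pass, with 7 higher and 4 lower of 21 (camera adjusted p = 0.50).

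Of 40 ribosomal protein genes, 38 rose and none fell, with a median of 0.38 (camera adjusted p = 6.1e-10, and adjusted p = 0.64 with an estimated correlation). These genes have many processed pseudogenes, and RPL7A rose by a log2 fold change of 0.56 in all exon reads and 0.50 in uniquely placed ones. In ribosome biogenesis and MYC targets 22 of 35 rose and 3 fell (camera adjusted p = 0.0013, and adjusted p = 0.64 with an estimated correlation), with BOP1 at a log2 fold change of 1.29 and POLR1A, the large subunit of RNA polymerase I, at 1.01. The median of that list was 0.21, 0.12 with library totals alone or upper-quartile scaling and 0.40 with a GC trend removed. The median of all genes moved to -0.09 in the first 2 of these settings and to 0.11 in the last. Heat shock genes rose in 14 of 17 cases and fell in 1, SERPINH1 (camera adjusted p = 4.3e-04, and adjusted p = 0.64 with an estimated correlation). HSPA8, a constitutive chaperone, rose by a log2 fold change of 1.15.

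Autophagy and lysosome genes had 20 higher and 7 lower members of 37 (camera adjusted p = 0.034, and adjusted p = 0.64 with an estimated correlation), and the call was lost in total and unique gene reads (camera adjusted p = 0.061 and 0.078, within a range of 0.0099 to 0.078 over 15 alternatives). Members that rose included the lysosomal cholesterol transporter NPC1 (log2 fold change 1.34), the proton pump subunit ATP6V1A (1.19) and the sialidase NEU1 (1.28). Those that fell included the autophagy kinases ULK1 (-1.36) and ULK2 (-1.64). The median of the list was 0.22, 0.13 with library totals alone or upper-quartile scaling and 0.37 with a GC trend removed. These values carry the move of the median of all genes, to -0.09 with either scaling and 0.11 with the GC trend removed.

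Interferon-stimulated genes were lower in 19 of 26 tested cases and higher in 1, IFIT5, with a median of -0.92 (camera adjusted p = 6.4e-04, and adjusted p = 0.64 with an estimated correlation). The median was -0.61 in uniquely placed gene reads. IFI35 (ENSG00000068079, chromosome 17, 41158742 to 41166473) fell from 14.9 ± 0.12 to 3.06 ± 0.0265 CPM, the RNA sensor DHX58 by 1.88 and IFITM1 by 1.57 on the log2 scale. Germline and cancer-testis genes, which are often silenced by DNA methylation, had 1 tested member of 46, TDRKH, which fell by 0.98. Of 18 tested tumour suppressors known to be methylated in ovarian cancer, 7 rose and 8 fell (camera adjusted p = 0.72). CDKN2B fell by 1.39 and ZMYND10 by 2.07, and HIC1 rose by a log2 fold change of 1.12.

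Stress response genes went both ways. In the list of unfolded protein and integrated stress response genes 15 of 32 fell and 9 rose, with a median of -0.48 (camera adjusted p = 0.049, and adjusted p = 0.64 with an estimated correlation). Those that fell included CHAC1 (-2.02), CEBPB (-1.65) and DDIT3 (-1.46), and those that rose included HSP90B1 (0.29), SDF2L1 (0.79) and CRELD2 (0.90). Branches of the response were not tested apart. The call was lost in 4 of 15 alternatives (size factors of the DESeq2 kind, upper-quartile scaling, and the removal of a length or a GC trend), and adjusted p ranged from 7.0e-04 to 0.065 over all 15. Without wogonin 3 the median was -0.27. TGF-beta and WNT targets fell in 11 of 18 cases and rose in 4 (camera adjusted p = 0.034, and adjusted p = 0.64 with an estimated correlation), led by the helix-loop-helix inhibitors ID1 (-2.03), ID2 (-2.02) and ID3 (-1.82). That call was lost with library totals alone, without a filter and with upper-quartile scaling (camera adjusted p = 0.058, 0.051 and 0.059, within a range of 0.0049 to 0.059).

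Mesenchymal genes fell in 9 of 20 cases and rose in 1, LOX, with a median of -0.25 (camera adjusted p = 0.036, and adjusted p = 0.64 with an estimated correlation). The transcription factors SNAI2 and TWIST1 fell by 1.26 and 0.65 on the log2 scale. The call was lost without DMSO 1 (camera adjusted p = 0.079, the highest of 15 alternatives that began at 0.0095), and the median was -0.13 with an exon length trend removed and -0.67 without a filter. Removing the length trend moved the median of all genes to 0.11, and the value of -0.13 carries that shift. Epithelial genes did not pass as a list (2 higher and 6 lower of 8, camera adjusted p = 0.12), and in it the tight junction genes TJP3 and TJP1 fell by 2.00 and 0.85.

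**Figure D2:**
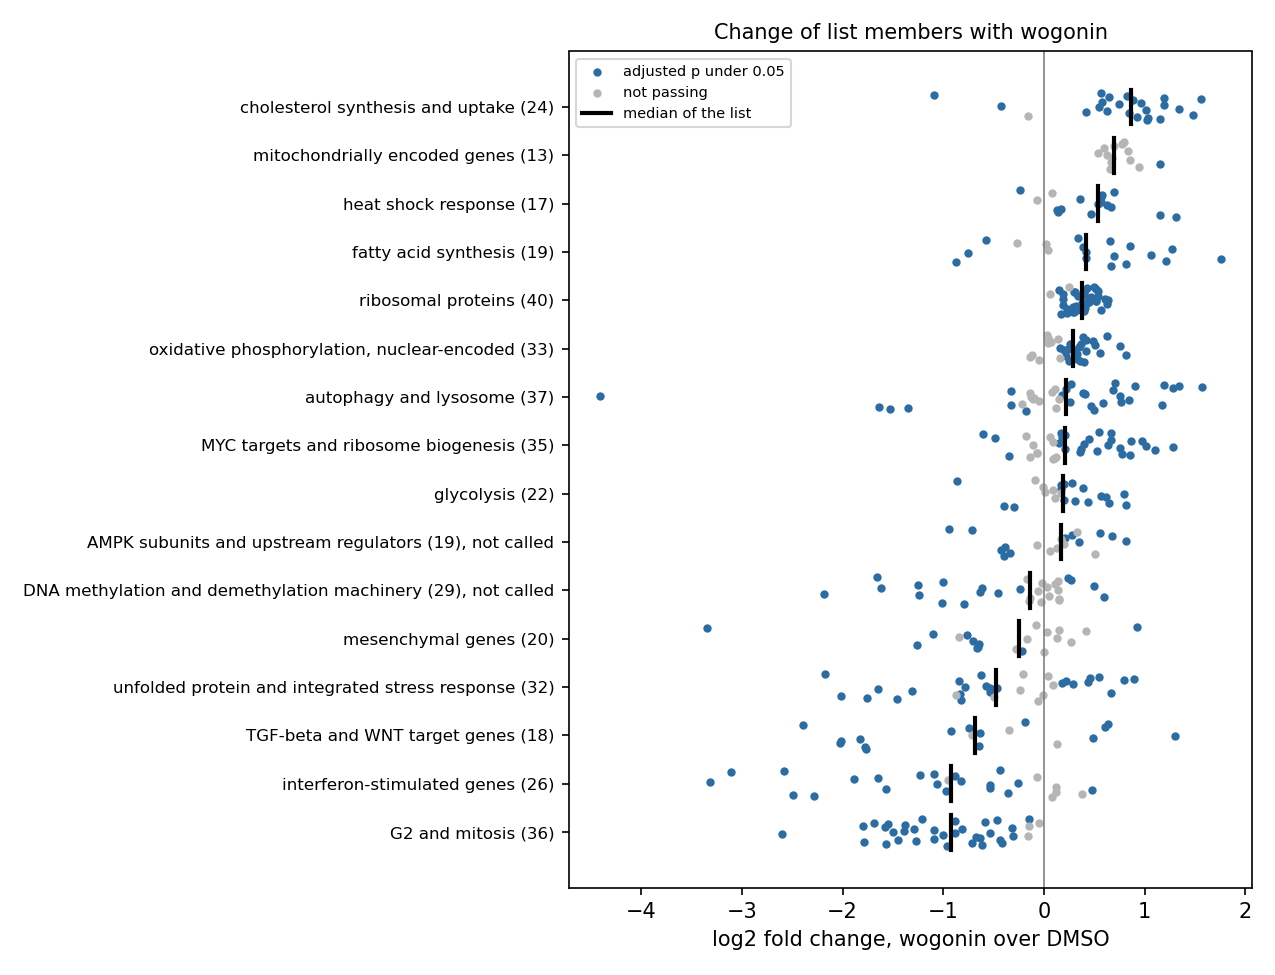
Log2 fold change with wogonin of every tested member of the 14 lists that passed the camera test, and of the DNA methylation and AMPK lists, which did not, with the number tested in brackets. Each point is a gene, blue where its adjusted p is under 0.05, and a black bar marks the list's median, from -0.92 for G2 and mitosis to 0.87 for cholesterol synthesis and uptake.

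In all, 14 of 35 tested lists passed, 9 as higher and 5 as lower. None passed with an estimated correlation, where the adjusted p was 0.64 for each of the 14. With 4 libraries that test has few degrees of freedom and little power. Interferon-stimulated genes had an estimated correlation of -0.0018, below the preset 0.01, and still went to 0.64. The shared value therefore does not decide whether correlation between genes accounts for the calls. The other 21 lists had camera adjusted p-values from 0.081 to 0.97, and 4 had too few tested members. Among marker lists of other cell types, 3 of 5 tested leukocyte genes fell, and fibroblast and smooth muscle genes had 2 higher and 4 lower of 10 (camera adjusted p = 0.17 and 0.76). No erythroid gene and 3 endothelial genes were tested.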

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

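The tests of intron reads in this part were chosen after the exon reads had been analysed, and those of the intron share after the share itself was seen. Introns took 7.96% of the reads of genes with exons in wogonin 3, above the 5.26% and 5.29% in the DMSO libraries and the 5.61% in wogonin 4. Genomic DNA would add reads to introns of silent and expressed genes alike. The density added over the DMSO mean in 5105 coding genes silent in DMSO was 0.096 of that added in 9421 expressed genes (95% bootstrap interval 0.067 to 0.13), below the bound of 0.5 set for it, which argues against it as the whole cause of the rise in wogonin 3. In wogonin 4 the density in the silent genes was 4.50 CPM of intron reads per Mb of intron, against 2.72 and 2.63 in DMSO 1 and 2 and 6.40 in wogonin 3, while that in expressed genes was 71.3 against 69.7 and 70.1 (109 in wogonin 3). A rise in introns of genes silent in DMSO was thus shared by both treated libraries, and its cause, a small share of DNA included, stays open, since these genes were picked for low counts in DMSO. The rise of the coding intron share in wogonin 4 was 0.10 of that in wogonin 3, a value computed from the shares that raised the question, so an effect of treatment of unequal size stays open too. A larger share of unspliced RNA in wogonin 3 was not tested.

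Reads in genes that the tables list without exons do not enter the exon counts. They enter the total and unique gene reads used as alternatives. Of 269 such genes tested in total gene reads, 82 were higher and 65 lower with wogonin (edgeR adjusted p under 0.05). Over all genes tested in total gene reads, 8990 of 15201 were called. Genes without exons were thus not called more often than genes at large. Chosen after their values were seen, NCBP2-AS2 rose from 16.5 ± 0.69 to 30.1 ± 1.27 CPM (SD, n = 2), and HMGB1P5, a pseudogene that can share reads with its parent, fell from 58.5 ± 2.04 to 31.5 ± 2.62 CPM. Without a stated strand setting, reads of an antisense gene cannot be told from those of its partner.

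The ratio of intron to exon reads was not part of the exon comparison, but it contains the exon counts, and a change of exon reads alone can move it. It was higher with wogonin in 604 and lower in 398 of 8680 coding genes (edgeR interaction test, adjusted p under 0.05). Chosen after its value was seen, HBP1 had a ratio change of 4.36 log2 units (SE 0.31) while its exon reads fell, and CYP4V2, whose exon reads rose, had a change of -3.85. Scaling was done separately for exon and intron reads, which removes a rise of the intron share in wogonin 3 that is even over genes. An uneven rise can still enter these calls, which was not tested.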

How the results depend on the processing

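Upper-quartile scaling, the newer quasi-likelihood method, the GC trend and the removal of mitochondrial genes were chosen after seeing the data. The count of changed genes ranged from 6701 (DESeq2) to 9141 (no filter) over all alternatives and from 7158 to 8166 with a library left out, where the lone library of a group is assumed to vary like the others. Requiring 1 log2 unit as well leaves 2186 genes, 849 higher and 1337 lower. That split was 1071 and 1099 with the length trend removed, 1051 and 1098 with the GC trend removed, 1353 and 1448 in total gene reads and 703 and 1578 with library totals alone. The share of higher calls was 50.6%, 42.4% with library totals alone, and 5269 of 8781 calls with the length trend and 5364 of 8936 with the GC trend removed. The length and GC trends moved the median of all genes to 0.11, and medians, signs and calls under them carry that shift. Both settings corrected the scaling between groups more than once, since the TMM factors were applied on top of trends fitted to library totals. Splits and lost calls under them therefore do not show a length or GC effect. Calls in the opposite direction numbered 21 in total gene reads, 22 in unique gene reads and 4 in unique exon reads, and 0 in the other settings. Of 126 named genes past the threshold, 117 kept call and direction in every alternative that tested them and none reversed. Most of them had been picked for a small adjusted p or a large change, which favours keeping the call. Of all 8577 calls, 6679 kept call and direction with DESeq2, 7580 in total gene reads and 7128 in unique gene reads. Of the 4 genes fixed by name that did not pass, PRKAA2 kept its sign and the others changed it in some settings. DNMT1 (0.03) was at -0.0652 with library totals alone, -0.0390 in total gene reads, -0.0172 in unique gene reads, -0.0651 with upper-quartile scaling, and between -0.0220 and 0.0555 with a library left out. TET3 (-0.03) was at 0.0798 and 0.0150 with the length and GC trend removed and between -0.0834 and 0.0224 with a library left out. TDG (-0.14) was at 0.00281 with the GC trend removed and between -0.234 and -0.0568 with a library left out. It passed with library totals alone or upper-quartile scaling (both -0.24). All genes shifted by a median of -0.0923 with library totals alone, -0.0922 with upper-quartile scaling and 0.105 with the length trend removed. The moves of DNMT1, TET3 and TDG printed for those settings were about as large, so they follow the zero point of the scale. The cause of the other shifts was not tested. Of the 14 called lists, 9 passed in every camera alternative, and between 11 and 15 lists passed in each. With an estimated correlation, a test of little power here, 0 lists passed. Fry's directional test called 22. It did not call 2 lists that camera called, unfolded protein and integrated stress response (fry adjusted p = 0.088) and mitochondrially encoded genes (fry adjusted p = 0.27). Ribosomal protein genes took 3.39% of exon reads in DMSO and 4.07% in wogonin, and 2.88% and 3.44% of unique exon reads, 3.21% and 3.81% of total gene reads and 2.73% and 3.22% of unique gene reads. The mitochondrial share in DMSO was 1.55%, and 1.83% and 1.91% in total and unique gene reads. No paired analysis was possible because the groups share no replicate numbers.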

Other observations

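The lists in this part were written after the exon results had been seen, and the tests that match random sets on exon change, or follow members that fell, were chosen after the values they concern. Genes of the translocon and of vesicle transport from the endoplasmic reticulum rose together, with 25 of 31 tested members higher and 1, COPB1, lower (median 0.58, camera adjusted p = 1.0e-07 over 7 lists, and adjusted p = 0.10 with an estimated correlation). SEC24D rose by a log2 fold change of 1.40, RER1 by 1.35 and SEC61A1 by 1.11. Clock genes went both ways, with 5 of 15 higher and 8 lower (camera adjusted p = 0.20). The labels give no treatment time for DMSO, so a difference in timing between the groups stays open for these genes and was not tested. The output factors DBP (-3.13) and TEF (-2.61) and the repressors NR1D2 (-2.39) and NR1D1 (-1.68) fell, while PER3 rose by a log2 fold change of 0.50 and BHLHE40 by 0.48. Genes downstream of ERK had 7 higher and 3 lower of 14, with EGR1 at 2.27 and SPRY4 at 1.78 (camera adjusted p = 0.13). SR proteins and core splicing factors had 13 higher and 11 lower of 38 (camera adjusted p = 0.91).

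Several of the genes with large falls, such as KLHL24, YPEL2 and KLF9, have been described as targets of FOXO transcription factors, which led to the hypothesis that such targets fell as a class. A list of FOXO factors and targets had 21 of 24 tested members lower and 1 higher. That count includes the genes whose falls had prompted the list, so it does not test the hypothesis. Among the 15 tested members whose values had not been seen, 12 were lower, including TXNIP (-2.18), PIK3IP1 (-2.14), FOXO1 (-1.62) and BCL6 (-1.74), and 1, SEPW1, was higher (camera adjusted p = 4.3e-05, and adjusted p = 0.10 with an estimated correlation). CDKN1B (-0.12) and SESN3 (-0.08) did not pass. FOXO1, FOXO3 and FOXO4 are the factors themselves. The list does not hold every described target, so the result covers the listed genes only. Described targets left out of it include CDKN1A (log2 fold change 2.12) and SOD2 (0.67), which rose, and BCL2L11 (-1.18), which fell. Their median of -1.20 lay below all of 10000 random sets matched on expression (0% of sets lower, middle 95% of sets -0.50 to 0.29). A length or GC trend is argued against, since the larger median with either removed was -1.21 relative to all genes (95% bootstrap interval -1.64 to -0.44), below the bound of -0.1. Lower FOXO-dependent transcription may account for this, and differences in feeding or density between the cultures, which the labels do not record, stay open and untested.

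HNRNP genes, which encode RNA-binding proteins of pre-mRNA processing, were lower in 16 of 22 tested cases and higher in 3. Their median was -0.44 (camera adjusted p = 4.3e-05, and adjusted p = 0.27 with an estimated correlation). HNRNPA3 was at -2.32, HNRNPD at -1.93 and HNRNPA1 at -1.66. The family was chosen after its exon values had been seen, so these p-values describe the fall and do not test it. The lower cases count both HNRNPUL2 (-0.17) and HNRNPUL2-BSCL2 (-0.50), an entry that by its name includes the same gene. Reads shared with pseudogenes and the 2 trends were tested first by the family's median, which was -0.38 in unique exon reads (95% bootstrap interval -1.13 to -0.16) and at most -0.38 relative to all genes with a trend removed (-1.08 to -0.15), so that both intervals crossed the bound of -0.3. Member by member over the 15 that fell and were tested in both columns, the median shift was -0.00067 of their fall in unique reads (-0.024 to 0.00015) and 0.035 with a trend removed (-0.051 to 0.049), which argues against either as the whole cause. The ratio of intron to exon reads in the family rose by a median of 0.74 log2 units, and was higher in 7 of 20 members and lower in 0 by the edgeR interaction test. Intron reads themselves moved little, with a median log2 change of 0.13 in the family against 0.04 in all genes, so the ratio rose mainly because exon reads fell. Its place above 99.99% of random sets matched on expression therefore largely restates that fall. The ratio also lay above that of 98.57% of sets matched on exon change. That leaves open both a shift to forms that keep introns and a loss of spliced transcripts at steady intron levels, and the test does not tell them apart.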
